A study of Mus musculus with 16 samples.

How the data were processed

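Macrophages and neutrophils from kidneys of infected WT and C5ar1-deficient mice were compared, with 4 mice in each of 4 groups and 16 libraries. Per the labels' protocols, cells were stained and sorted by flow cytometry to a purity above 90%. Macrophages were CD45+ cells negative for CD3, CD19, NKp46 and Ly6G and positive for CD11b and a further macrophage antigen, with high MHC class II, and neutrophils were CD45+ Ly6G+ CD11b+. Also per the labels' protocols, complementary DNA was amplified with the SMART-Seq v4 kit, libraries were made with Nextera XT, and 50-base single-end reads from a HiSeq3000 were mapped with STAR v2.5.2. The submitters' processing notes name the builds GRCm38 and mm10 and the tool limma. The counting tool, the gene lengths and the scaling method are not given in the sources used here.

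The authors deposited log2 values in 2 tables, 1 per cell type, which were normalised separately. The unit was worked out from the deposited log2 values: the lowest is 0, and after removing the log the values times exon length cluster at multiples of 1 step per library for some low genes. Scores of that clustering were 8.42 to 16.5, against at most 4.44 when exon lengths were shuffled among genes. The values were therefore treated as log2(value + 1) of an amount per kilobase of exon. Only 21.1% of low values in the macrophage table and 23.4% in the neutrophil table lay within 0.05 of a whole number of steps, so whole reads were not recovered, no count model was used and the read depth is unknown. The estimated step, which is larger for a shallower library, was 0.206 per kilobase in WT macrophage library 1, 0.0287 to 0.0872 in the other macrophage libraries and 0.0278 to 0.107 in the neutrophil libraries. The kit does not mark strand, so reads of overlapping and antisense genes cannot be separated.

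Genes whose symbol stood more than once in a table were left out (2 entries for macrophages, 3 for neutrophils). All 8 columns of each table matched a sample. Symbols were matched to GENCODE M21 (GRCm38) for coordinates, which 96.5% of macrophage and 96.6% of neutrophil genes had. Genes above 0 in at least 4 of the 8 libraries of a table were tested, 10856 for macrophages and 9694 for neutrophils. KO was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between cell types was the contrast of the 2 genotype effects in 1 limma fit of 16 libraries and 9123 genes, so that a shift common to a table cancels. Every adjusted p of a gene is from limma. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures were drawn with Matplotlib 3.10.9.

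Before the data were examined, the tests, the alternatives, the rule for named genes and 35 gene lists were fixed. The named genes are C5ar1, then per cell type the 10 largest rises and 10 largest falls among genes past the threshold with a mean at or above the median of tested genes and no overlap between the 4 KO and the 4 WT values, leaving out unnamed or predicted genes. The rule adds up to 4 members with the smallest p from each list described, of which 3 were used, the 10 largest differences between cell types among genes past the threshold with a mean over the 16 libraries at or above the median of tested genes, leaving out unnamed or predicted genes, and genes past the threshold within 5 Mb of C5ar1. The 12 lists described in detail were chosen after their values had been seen, and all others are given by their counts. Lists with at least 5 tested genes were tested by camera with a preset correlation of 0.01, adjusted over the lists of 1 cell type, and by camera with an estimated correlation and by fry. Camera asks whether the members move more than other genes, and fry whether they move, on balance, one way. The lists cover glycolysis, HIF-1 targets, oxidative phosphorylation, oxidant enzymes, granule proteins, phagocytosis, fungal and bacterial sensing, complement, chemotactic receptors, cytokines, NF-kB, both interferon types, MHC class II, repair, apoptosis, endoplasmic reticulum stress, immediate early genes, cholesterol synthesis, the cell cycle, ribosomal proteins, resident macrophages, monocytes, markers of neutrophils, macrophages, dendritic, T, B and natural killer cells, epithelium, endothelium, fibroblasts, erythroid cells and platelets, and sex-linked genes.

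The tests were checked on simulated data in 10 simulations with 200 changed genes each. The simulated noise was independent between genes, with 1 spread per gene in all libraries of a table. It thus held no correlated genes and no deviating library such as WT macrophage library 1. The changed genes were also far fewer than the 4246 that passed in neutrophils, so the rates may differ in the real data. At a log2 change of 1 the test recovered 23.4% of changed genes in macrophages, 76.5% in neutrophils and 20.3% for the difference between cell types, and at a log2 change of 2 it recovered 70.2%, 98.6% and 75.4%. Among the calls, 5.98%, 4.77% and 9.95% were unchanged genes, in the same order. The alternatives were other normalisations, pseudocounts and filters, limma without a trend or with sample weights, 1 fit of all 16 libraries, the mouse number as a block, a minimum fold change, another threshold, and leaving out each library in turn. Chance was assessed by all 35 splits of the 8 libraries of a table into 4 and 4, or by 100 drawn relabellings for the difference. The sex of the mice is not in the labels. No library was left out of the main tests.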

Results

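Kidney phagocytes were profiled by RNA sequencing on day 2 of systemic infection with the yeast Candida albicans, in wild-type (WT) mice and in mice lacking C5ar1 (KO), the receptor for the complement fragment C5a. Macrophages and neutrophils were sorted from the kidney, giving 4 groups with 4 mice each and 16 libraries. The macrophage gate required high surface MHC class II, so MHC class II transcripts in those cells were read from a population chosen on that protein. Expression is given as the deposited log2(value + 1), where the value behaves as reads per kilobase of exon. The 2 tables were normalised separately, and each test of KO against WT stayed within 1 table. Fold changes are on this log2 scale, which understates changes of low genes. Read depth per library is unknown, because most low values lie off whole-read steps. WT macrophage library 1 stood apart from the rest. It had 142 tested genes at 0, against 10 to 31 in the other WT macrophage libraries, and its correlation across genes with the other macrophage libraries was 0.730 to 0.819. The ribosomal RNA transcript Rn45s and Lars2 together made up 6.78% of its summed linear values, against at most 0.230% in the other macrophage libraries.

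C5ar1 itself was read first, as a check of the genotype labels. The gene lies on chromosome 7 at 16246743 to 16259540 (GRCm38). In macrophages its log2 value was 6.80 ± 0.66 in WT and 2.22 ± 0.27 in KO (SD, n = 4), a log2 fold change of -4.58 ± 0.33 (SE), adjusted p = 4.15e-04, limma. In neutrophils it was 9.23 ± 0.39 in WT and 4.08 ± 0.46 in KO (SD, n = 4), a log2 fold change of -5.15 ± 0.25 (SE), adjusted p = 2.11e-07, limma. Every KO library lay below every WT library in both cell types, so no library went against its label. Some C5ar1 signal remained in the KO cells, at log2 values of 1.91 to 2.5 in macrophages and 3.60 to 4.52 in neutrophils.

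**Figure D1:**
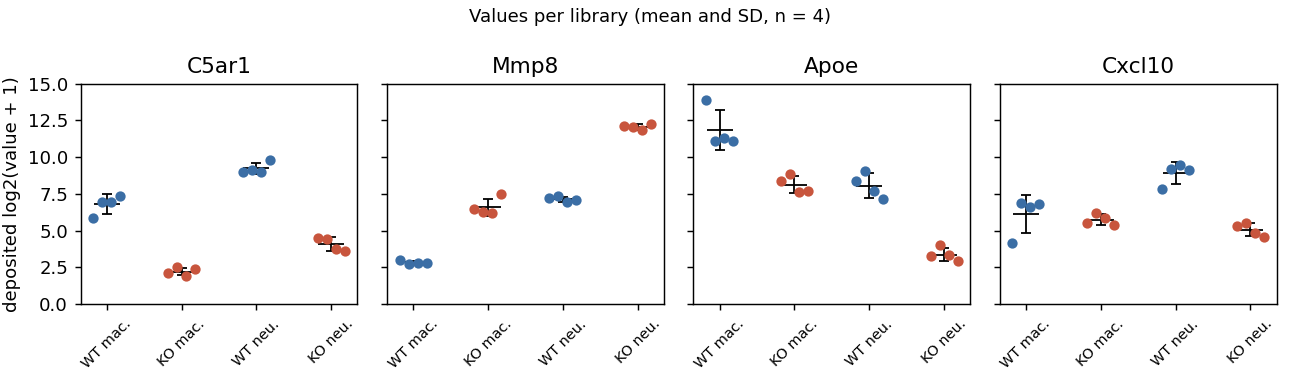
Deposited log2(value + 1) of C5ar1, Mmp8, Apoe and Cxcl10 in each library, with 1 point per library and black marks for the mean and SD of 4 libraries per group. C5ar1 and Apoe lay lower in KO than in WT in both cell types, Mmp8 lay higher in both, and Cxcl10 fell by 3.86 in neutrophils. The 2 tables were normalised separately, so levels are not comparable between cell types.

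The first comparison asked how macrophages from KO mice differed from those of WT mice. Whether a difference arose from loss of the receptor in the sorted cells themselves was not tested. As lists, glycolysis, targets of the hypoxia-inducible factor HIF-1 and cytokines and chemokines were shifted higher in KO macrophages, and MHC class II and interferon-inducible genes lower. These shifts passed camera with the preset correlation and not with an estimated correlation, and many members did not pass alone. In all, 630 of 10856 tested genes passed limma at an adjusted p below 0.05, of which 400 were higher and 230 lower in KO, with 343 and 182 of them changed by more than 1 log2 unit. The ranking that follows covers genes with a mean at or above the median of tested genes and no overlap between KO and WT values, C5ar1 left out. Within it, the largest rises were those of Mt2, a metal-binding metallothionein (5.87 ± 0.72 (SE), adjusted p = 0.00309), of the chemokine Cxcl3 (5.05 ± 0.42 (SE), adjusted p = 7.06e-04) and of Il1r2, a decoy receptor for interleukin-1 (4.50 ± 0.45 (SE), adjusted p = 0.00136). Next came the serine protease gene Htra4 (4.48), the chemokine Cxcl13 (4.25), the acute-phase gene Saa3 (3.96), the siderophore-binding Lcn2 (3.95), the inducible nitric oxide synthase Nos2 (3.93), Hilpda (3.81) and the collagenase Mmp8 (3.76). Saa3 has close paralogs, and its value is uncertain to the extent that reads were split between them. Within the same ranking the largest falls were those of Kap, a transcript of kidney tubules (-4.06 ± 0.60 (SE), adjusted p = 0.00703), of the apolipoprotein Apoe (-3.72 ± 0.62 (SE), adjusted p = 0.0117) and of Ly6c2, a surface protein of inflammatory monocytes (-3.72 ± 0.26 (SE), adjusted p = 4.15e-04). They were followed by Ly6e (-3.45), Fam26f (-3.07), Ltb (-3.01), the MHC class II chaperone H2-DMb1 (-2.77), Clec12a (-2.59), Rnase6 (-2.58) and Clec4b1 (-2.47). WT library 1 had higher values of Apoe, Mt2 and Saa3 than the other 3 WT libraries.

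The glycolysis list was shifted higher in KO macrophages: 10 of 20 rose, 0 fell and 10 did not pass (17 higher and 0 lower adjusted over the list alone). The median log2 fold change was 1.25 (adjusted p = 7.18e-10, camera, and adjusted p = 0.159 with an estimated correlation). The lactate exporter Slc16a3 (1.94 ± 0.27 (SE), adjusted p = 0.00505), the glucose transporter Slc2a1 (2.70 ± 0.43 (SE), adjusted p = 0.00971) and lactate dehydrogenase Ldha (1.59 ± 0.26 (SE), adjusted p = 0.0112) were its members with the smallest p. Among the HIF-1 targets, 11 of 19 rose, 0 fell and 8 did not pass (15 higher and 0 lower adjusted over the list alone). The median was 1.48 (adjusted p = 3.13e-11, camera, and adjusted p = 0.159 with an estimated correlation). Besides Hilpda (adjusted p = 7.06e-04), the vasoactive peptide gene Adm (3.05 ± 0.40 (SE), adjusted p = 0.00402) and the collagen hydroxylase P4ha2 (1.83 ± 0.25 (SE), adjusted p = 0.00505) rose. Slc2a1, Ldha and the mean of the HIF-1 targets were lower in WT library 1 than in the other WT libraries. Without that library the medians of the 2 lists were 1.11 and 1.24, and 17 and 15 members rose. Of the inflammatory cytokines and chemokines, 13 of 31 rose, 2 fell and 16 did not pass (16 higher and 4 lower adjusted over the list alone). The median was 0.79 (adjusted p = 4.70e-05, camera, and adjusted p = 0.159 with an estimated correlation). Cxcl1 (3.05 ± 0.29 (SE), adjusted p = 0.00123) and Il10, which encodes an anti-inflammatory cytokine (2.99 ± 0.30 (SE), adjusted p = 0.00135), rose with Cxcl3. In the list of the NADPH oxidase and related oxidant enzymes, 2 of 12 rose, 0 fell and 10 did not pass (3 higher and 0 lower adjusted over the list alone). The median was 0.33 (adjusted p = 0.0231, camera, and adjusted p = 0.211 with an estimated correlation). The members that rose were Nos2 (adjusted p = 0.00505), which makes nitric oxide, and the mitochondrial superoxide dismutase Sod2 (2.04 ± 0.33 (SE), adjusted p = 0.0106), neither of them an oxidase subunit. The proton channel Hvcn1 had 1.51 ± 0.38 (SE), adjusted p = 0.0507.

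The lists of MHC class II and interferon-inducible genes were shifted lower in KO macrophages, a population gated on high MHC class II protein, although most interferon-inducible members did not pass. The MHC class II list also holds the regulator Ciita and the costimulatory genes Cd40, Cd80 and Cd86. In this list, 0 of 13 rose, 8 fell and 5 did not pass (2 higher and 8 lower adjusted over the list alone). The median was -1.54 (adjusted p = 3.93e-07, camera, and adjusted p = 0.159 with an estimated correlation). Ciita, the master regulator of this family (-3.76 ± 0.32 (SE), adjusted p = 7.67e-04), H2-DMb1 (adjusted p = 0.0022) and H2-DMb2 (-2.42 ± 0.28 (SE), adjusted p = 0.0025) fell. In the interferon-gamma list, 1 of 25 rose, 6 fell and 18 did not pass (1 higher and 16 lower adjusted over the list alone). The median was -1.10 (adjusted p = 9.75e-11, camera, and adjusted p = 0.159 with an estimated correlation). Apart from Ciita, the guanylate-binding protein Gbp8 (-2.67 ± 0.34 (SE), adjusted p = 0.00353) and the chemokine Cxcl9 (-1.93 ± 0.30 (SE), adjusted p = 0.00945) fell. Of the type I interferon genes, 0 of 37 rose, 7 fell and 30 did not pass (0 higher and 21 lower adjusted over the list alone). The median was -0.90 (adjusted p = 9.32e-13, camera, and adjusted p = 0.159 with an estimated correlation). Stat1 (-1.78 ± 0.20 (SE), adjusted p = 0.00206), Xaf1 (-1.38 ± 0.22 (SE), adjusted p = 0.00947) and Parp14 (-1.04 ± 0.17 (SE), adjusted p = 0.00947) fell. For cholesterol synthesis, 0 of 22 rose, 4 fell and 18 did not pass (0 higher and 4 lower adjusted over the list alone). The median was -0.30 (adjusted p = 0.00431, camera, and adjusted p = 0.159 with an estimated correlation). Stard4 (-1.05), Srebf2 (-0.96) and Dhcr24 (-1.85) fell.

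Some markers of other cells moved with genotype in the macrophage sort. The list of neutrophil granule proteins was shifted higher in KO: 6 of 15 rose, 0 fell and 9 did not pass (8 higher and 1 lower adjusted over the list alone). The median was 1.27 (adjusted p = 3.37e-05, camera, and adjusted p = 0.217 with an estimated correlation). Among them were Mmp8 (adjusted p = 6.36e-04), Lcn2 (adjusted p = 0.00288) and the granule protein Ngp (3.39 ± 0.44 (SE), adjusted p = 0.00398). Of the neutrophil markers, which share members with that list, 5 of 14 rose, 0 fell and 9 did not pass (9 higher and 0 lower adjusted over the list alone). The median was 1.29 (adjusted p = 1.18e-06, camera, and adjusted p = 0.185 with an estimated correlation). S100a8 and S100a9, abundant transcripts of neutrophils, together took 0.218% to 0.679% of the summed linear values in KO macrophages and 0.0694% to 0.183% in WT. The list of kidney epithelial markers was shifted lower in KO: 0 of 13 rose, 5 fell and 8 did not pass (1 higher and 9 lower adjusted over the list alone). The median was -1.35 (adjusted p = 4.03e-06, camera, and adjusted p = 0.159 with an estimated correlation). Those with the smallest p were the proximal tubule genes Miox (-3.97 ± 0.27 (SE), adjusted p = 4.15e-04) and Slc34a1 (-3.54 ± 0.40 (SE), adjusted p = 0.00238) beside Kap (adjusted p = 0.00703). Of the macrophage markers, 0 of 15 rose, 4 fell and 11 did not pass (1 higher and 5 lower adjusted over the list alone). The median was -0.18 (adjusted p = 0.0263, camera, and adjusted p = 0.159 with an estimated correlation). Those with the smallest p were the MHC class II genes H2-Ab1 (-2.27) and H2-Aa (-1.99), and Apoe (adjusted p = 0.0117). Without WT library 1 this list had a median of 0.05 and adjusted p = 0.221.

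The other lists tested in macrophages were as follows. For phagocytosis and lysosomes, 3 of 25 rose and 0 fell (4 higher and 1 lower adjusted over the list alone). The median was 0.44 (adjusted p = 0.0162, camera, and adjusted p = 0.288 with an estimated correlation). For C-type lectin and Toll-like receptor sensing, 3 of 25 rose and 0 fell (9 higher and 1 lower adjusted over the list alone). The median was 0.69 (adjusted p = 1.25e-04, camera, and adjusted p = 0.22 with an estimated correlation). For NF-kB responses, 4 of 25 rose and 0 fell (10 higher and 2 lower adjusted over the list alone). The median was 0.57 (adjusted p = 4.95e-04, camera, and adjusted p = 0.288 with an estimated correlation). For alternative activation and repair, 8 of 23 rose and 2 fell (10 higher and 3 lower adjusted over the list alone). The median was 0.32 (adjusted p = 0.0468, camera, and adjusted p = 0.172 with an estimated correlation). For apoptosis and survival, 3 of 30 rose and 0 fell (8 higher and 0 lower adjusted over the list alone). The median was 0.48 (adjusted p = 0.0225, camera, and adjusted p = 0.29 with an estimated correlation). Leaving out 1 library moved that median to between 0.15 and 0.59, and the call was lost in 4 other settings, the estimated correlation included. For the cell cycle, 0 of 30 rose and 0 fell (0 higher and 0 lower adjusted over the list alone). The median was -0.52 (adjusted p = 2.63e-04, camera, and adjusted p = 0.47 with an estimated correlation). Leaving out 1 library moved it to between -0.84 and -0.24, and the call was lost in 4 other settings, the estimated correlation included. The list mean varied among KO libraries, with an SD of 0.78 against 0.39 in WT. For ribosomal proteins, 0 of 35 rose and 0 fell (0 higher and 0 lower adjusted over the list alone). The median was -0.66 (adjusted p = 0.0038, camera, and adjusted p = 0.587 with an estimated correlation). For dendritic cell markers, 1 of 11 rose and 3 fell (1 higher and 5 lower adjusted over the list alone). The median was -0.47 (adjusted p = 0.0041, camera, and adjusted p = 0.211 with an estimated correlation). For natural killer cell markers, 1 of 5 rose and 4 fell (1 higher and 4 lower adjusted over the list alone). The median was -1.22 (adjusted p = 0.00859, camera, and adjusted p = 0.211 with an estimated correlation). For endothelial markers, 0 of 8 rose and 0 fell (0 higher and 1 lower adjusted over the list alone). The median was -0.56 (adjusted p = 0.0225, camera, and adjusted p = 0.234 with an estimated correlation). In the lists not past the threshold the results were these. For oxidative phosphorylation, 0 of 31 rose and 0 fell (0 higher and 0 lower adjusted over the list alone). The median was -0.25 (adjusted p = 0.343, camera). For complement and its receptors, 1 of 15 rose and 1 fell (1 higher and 1 lower adjusted over the list alone). The median was 0.21 (adjusted p = 0.57, camera). For chemotactic receptors, 3 of 17 rose and 1 fell (4 higher and 3 lower adjusted over the list alone). The median was 0.26 (adjusted p = 0.428, camera). For endoplasmic reticulum stress, 2 of 20 rose and 0 fell (2 higher and 0 lower adjusted over the list alone). The median was 0.37 (adjusted p = 0.0568, camera). For immediate early and heat shock genes, 3 of 25 rose and 2 fell (7 higher and 7 lower adjusted over the list alone). The median was -0.0031 (adjusted p = 0.57, camera). For resident macrophages, 0 of 19 rose and 1 fell (2 higher and 4 lower adjusted over the list alone). The median was -0.16 (adjusted p = 0.322, camera). For monocytes, 3 of 20 rose and 2 fell (7 higher and 5 lower adjusted over the list alone). The median was 0.34 (adjusted p = 0.57, camera). Lists with fewer than 5 tested genes had no list test: 1 rose and 0 fell of 3 T cell markers, 0 rose and 0 fell of 3 B cell markers, 0 rose and 0 fell of 4 fibroblast markers, 1 rose and 0 fell of 2 platelet markers, 0 rose and 0 fell of 4 sex-linked genes, and 0 erythroid markers were tested. In total 22 of 29 tested lists passed camera with the preset correlation, 11 higher and 11 lower in KO, 20 passed fry, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.159. The macrophage count of genes depended on single libraries. It was 1882 without WT library 1, 232 without WT library 2, 237 without WT library 3, 166 without KO library 1, 208 without KO library 2 and 228 without KO library 4. Some named genes lost their call without a single library, with the highest adjusted p given: Saa3 (adjusted p = 0.0838 without KO library 1), Ltb (adjusted p = 0.0783 without KO library 1), Clec12a (adjusted p = 0.0556 without KO library 4), Clec4b1 (adjusted p = 0.0641 without KO library 1) and Ldha (adjusted p = 0.0602 without KO library 1). The same held for Sod2 (adjusted p = 0.0528 without KO library 1), Parp14 (adjusted p = 0.0552 without KO library 1), Stard4 (adjusted p = 0.0639 without KO library 1), Srebf2 (adjusted p = 0.112 without KO library 1) and Dhcr24 (adjusted p = 0.096 without KO library 1). Of the 8 fits without 1 library, the call was lost in 6 for Saa3 and Srebf2 and in 5 for Dhcr24. It was lost in 4 for Ltb and Clec4b1, 3 for Stard4, 2 for Clec12a, and 1 each for Ldha, Sod2 and Parp14. Lists that lost their call in this way were oxidant enzymes (adjusted p = 0.0585 without WT library 1), ribosomal proteins (adjusted p = 0.944 without WT library 1), alternative activation (adjusted p = 0.126 without WT library 2) and endothelial markers (adjusted p = 0.0594 without WT library 2). Alternative activation lost it in 4 of these fits and endothelial markers in 2.

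The second comparison asked the same of the neutrophils, where many more genes passed than in macrophages. That contrast is no measure of a larger response. On simulated data with a log2 change of 1, the test recovered 23.4% of changed genes in macrophages and 76.5% in neutrophils. Without WT macrophage library 1 the macrophage count rose from 630 to 1882. In KO neutrophils most granule protein, glycolysis and HIF-1 target genes rose, and most interferon-inducible, MHC class II and cytokine and chemokine genes fell. Of 9694 tested genes 4246 passed limma at an adjusted p below 0.05, with 2309 higher and 1937 lower in KO, and 633 and 639 changed by more than 1 log2 unit. With the ranking limited in the same way, the largest rise was that of Ngp, a protein of neutrophil granules, whose log2 value was 4.95 ± 0.55 in WT and 12.49 ± 0.88 in KO (SD, n = 4; log2 fold change 7.54 ± 0.39 (SE), adjusted p = 3.44e-07, limma). It was followed by Stfa3, which encodes a cysteine protease inhibitor (5.67 ± 0.40 (SE), adjusted p = 1.67e-06), Bcl2l15 (5.65 ± 0.35 (SE), adjusted p = 6.98e-07), the chitinase-like Chil3 (5.49), the acute-phase glycoprotein Orm1 (5.38), Mmp8 (4.92), the surface glycoprotein Cd177 (4.83), the cathelicidin Camp (4.73), Ifitm6 (4.65) and Stfa2 (4.54). Stfa2 and Stfa3 belong to a family of near-identical genes, so their separate values are uncertain. Within that ranking the largest falls were those of Miox (-5.51 ± 0.29 (SE), adjusted p = 3.44e-07), Apoe (-4.69 ± 0.36 (SE), adjusted p = 2.52e-06) and Kap (-4.44 ± 0.66 (SE), adjusted p = 2.81e-04). After them came the gluconeogenic enzyme Pck1 (-4.28), Acy3 (-4.18), Keg1 (-4.16), the chemokine Cxcl11 (-4.09), the phosphate transporter Slc34a1 (-4.03), Cxcl10 (-3.86) and Gbp5 (-3.81). Several of the falls were in genes of the proximal tubule, among them Miox, Kap and Slc34a1.

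Nearly all granule protein genes rose in KO neutrophils: 18 of 19 rose, 1 fell and 0 did not pass (18 higher and 1 lower adjusted over the list alone). The median log2 fold change was 2.42 (adjusted p = 5.40e-11, camera, and adjusted p = 0.159 with an estimated correlation). Among them were Mmp8 (adjusted p = 1.57e-08), Ngp (adjusted p = 3.44e-07) and Cd177 (adjusted p = 6.50e-07). Of the neutrophil markers, 13 of 16 rose, 0 fell and 3 did not pass (13 higher and 0 lower adjusted over the list alone). The median was 2.5 (adjusted p = 1.65e-08, camera, and adjusted p = 0.251 with an estimated correlation). S100a8 and S100a9 together took 30.4% to 44.2% of the summed linear values in KO neutrophils and 12.9% to 18.8% in WT. For glycolysis, 17 of 20 rose, 0 fell and 3 did not pass (17 higher and 0 lower adjusted over the list alone). The median was 1.37 (adjusted p = 4.69e-09, camera, and adjusted p = 0.251 with an estimated correlation). Its members with the smallest p were the glucose phosphate isomerase Gpi1 (2.23 ± 0.17 (SE), adjusted p = 2.52e-06), Pgk1 (1.44) and Pgam1 (1.41). Of the HIF-1 targets, 16 of 17 rose, 0 fell and 1 did not pass (16 higher and 0 lower adjusted over the list alone). The median was 1.49 (adjusted p = 3.86e-09, camera, and adjusted p = 0.251 with an estimated correlation). Hilpda (3.54 ± 0.30 (SE), adjusted p = 5.02e-06), Higd1a (2.25) and the oxygen sensor Egln1 (1.80) had the smallest p. In the oxidant enzyme list, 7 of 13 rose, 1 fell and 5 did not pass (8 higher and 1 lower adjusted over the list alone). The median was 0.51 (adjusted p = 0.0391, camera, and adjusted p = 0.286 with an estimated correlation). Nos2 (3.85 ± 0.25 (SE), adjusted p = 8.76e-07), the myeloperoxidase Mpo (1.05) and Rac2 (1.04) rose, while the median of this list was -0.02 after quantile normalisation. For cholesterol synthesis, 10 of 21 rose, 2 fell and 9 did not pass (10 higher and 2 lower adjusted over the list alone). The median was 0.53 (adjusted p = 0.141, camera). Srebf2 (1.46), Pmvk (1.25) and Msmo1 (1.40) rose.

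Every tested member of the interferon-gamma list fell in KO neutrophils: 0 of 24 rose, 24 fell and 0 did not pass (0 higher and 24 lower adjusted over the list alone). The median was -2.00 (adjusted p = 1.61e-17, camera, and adjusted p = 0.159 with an estimated correlation). The guanylate-binding proteins Gbp3 (-3.56 ± 0.16 (SE), adjusted p = 1.36e-07) and Gbp5 (adjusted p = 7.03e-07) and the GTPase Tgtp2 (-2.08), which has a close paralog, led it. Of the type I interferon genes, 0 of 37 rose, 28 fell and 9 did not pass (0 higher and 30 lower adjusted over the list alone). The median was -1.13 (adjusted p = 5.40e-13, camera, and adjusted p = 0.251 with an estimated correlation). Stat1 (-2.27 ± 0.15 (SE), adjusted p = 1.06e-06), Ifi47 (-3.63) and Cmpk2 (-2.13) fell. In the MHC class II list, with Ciita and the costimulatory genes included, 0 of 13 rose, 10 fell and 3 did not pass (0 higher and 10 lower adjusted over the list alone). The median was -2.06 (adjusted p = 5.54e-06, camera, and adjusted p = 0.251 with an estimated correlation). H2-DMb1 (-2.77 ± 0.25 (SE), adjusted p = 9.41e-06), H2-DMb2 (-2.06) and the costimulatory receptor Cd40 (-2.5) fell. Among cytokines and chemokines, 4 of 30 rose, 17 fell and 9 did not pass (4 higher and 17 lower adjusted over the list alone). The median was -1.18 (adjusted p = 4.31e-04, camera, and adjusted p = 0.355 with an estimated correlation). Il10 rose (3.10 ± 0.24 (SE), adjusted p = 2.83e-06), whereas Cxcl10 (adjusted p = 6.01e-06) and Il15 (-2.37 ± 0.22 (SE), adjusted p = 9.60e-06) fell. Macrophage markers were lower in the same KO libraries: 0 of 15 rose, 12 fell and 3 did not pass (0 higher and 12 lower adjusted over the list alone). The median was -1.16 (adjusted p = 3.21e-05, camera, and adjusted p = 0.251 with an estimated correlation). They included Apoe (adjusted p = 2.52e-06), the invariant chain Cd74 (-2.54 ± 0.30 (SE), adjusted p = 5.75e-05) and H2-Aa (-2.63), which are also MHC class II genes or lie near C5ar1, and the complement genes C1qa (-1.14), C1qb (-1.16) and C1qc (-1.28), chosen here after their values were seen. Kidney epithelial markers were lower too: 0 of 18 rose, 14 fell and 4 did not pass (1 higher and 14 lower adjusted over the list alone). The median was -1.84 (adjusted p = 3.20e-08, camera, and adjusted p = 0.251 with an estimated correlation). Miox (adjusted p = 3.44e-07), Ttc36 (-4.07) and Slc34a1 (adjusted p = 1.32e-06) had the smallest p.

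The other lists that passed in neutrophils were all lower in KO. For immediate early and heat shock genes, 1 of 26 rose and 8 fell (1 higher and 8 lower adjusted over the list alone). The median was -0.33 (adjusted p = 0.0338, camera, and adjusted p = 0.518 with an estimated correlation). For the cell cycle, 0 of 17 rose and 12 fell (0 higher and 13 lower adjusted over the list alone). The median was -0.57 (adjusted p = 2.45e-04, camera, and adjusted p = 0.286 with an estimated correlation). For resident macrophages, 2 of 18 rose and 11 fell (2 higher and 11 lower adjusted over the list alone). The median was -0.67 (adjusted p = 0.00177, camera, and adjusted p = 0.286 with an estimated correlation). For dendritic cell markers, 0 of 7 rose and 5 fell (0 higher and 6 lower adjusted over the list alone). The median was -0.79 (adjusted p = 0.00157, camera, and adjusted p = 0.251 with an estimated correlation). For natural killer cell markers, 0 of 5 rose and 4 fell (0 higher and 4 lower adjusted over the list alone). The median was -1.34 (adjusted p = 0.00778, camera, and adjusted p = 0.386 with an estimated correlation). The macrophage share of 13.3% read from macrophage markers in WT neutrophils would cover 5.52 of the cell cycle fall and 2.70 of the MHC class II fall. Both are more than the whole WT level of those genes, so that share is too high for them. The lists that did not pass were these. For oxidative phosphorylation, 1 of 31 rose and 2 fell (0 higher and 0 lower adjusted over the list alone). The median was -0.07 (adjusted p = 0.49, camera). For phagocytosis and lysosomes, 11 of 25 rose and 3 fell (11 higher and 3 lower adjusted over the list alone). The median was 0.34 (adjusted p = 0.0608, camera). For C-type lectin and Toll-like receptor sensing, 5 of 25 rose and 6 fell (5 higher and 6 lower adjusted over the list alone). The median was -0.03 (adjusted p = 0.62, camera). For complement and its receptors, 4 of 15 rose and 8 fell (5 higher and 8 lower adjusted over the list alone). The median was -0.61 (adjusted p = 0.384, camera). For chemotactic receptors, 4 of 19 rose and 6 fell (5 higher and 6 lower adjusted over the list alone). The median was 0.08 (adjusted p = 0.62, camera). For NF-kB responses, 1 of 25 rose and 5 fell (1 higher and 5 lower adjusted over the list alone). The median was -0.11 (adjusted p = 0.163, camera). For alternative activation and repair, 8 of 20 rose and 3 fell (8 higher and 3 lower adjusted over the list alone). The median was 0.22 (adjusted p = 0.219, camera). For apoptosis and survival, 4 of 29 rose and 6 fell (4 higher and 6 lower adjusted over the list alone). The median was -0.02 (adjusted p = 0.776, camera). For endoplasmic reticulum stress, 7 of 21 rose and 1 fell (7 higher and 1 lower adjusted over the list alone). The median was 0.04 (adjusted p = 0.384, camera). For ribosomal proteins, 1 of 32 rose and 1 fell (0 higher and 1 lower adjusted over the list alone). The median was -0.03 (adjusted p = 0.49, camera). For monocytes, 7 of 20 rose and 5 fell (7 higher and 6 lower adjusted over the list alone). The median was -0.14 (adjusted p = 0.62, camera). For T cell markers, 2 of 5 rose and 3 fell (2 higher and 3 lower adjusted over the list alone). The median was -0.61 (adjusted p = 0.394, camera). For endothelial markers, 0 of 5 rose and 2 fell (0 higher and 2 lower adjusted over the list alone). The median was -0.34 (adjusted p = 0.103, camera). The median and the mean of the members differed in sign for chemotactic receptors (mean -0.25), monocytes (mean 0.42) and apoptosis and survival (mean 0.03). Lists with fewer than 5 tested genes gave 0 rose and 1 fell of 3 B cell markers, 1 rose and 0 fell of 3 fibroblast markers, 0 rose and 0 fell of 2 platelet markers, 0 rose and 0 fell of 4 sex-linked genes, and 0 erythroid markers were tested. In total 16 of 30 tested lists passed camera with the preset correlation, 5 higher and 11 lower in KO, 22 passed fry, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.159. Without a single library the oxidant enzymes (adjusted p = 0.0853 at most, without KO library 3) and the immediate early genes (adjusted p = 0.0951 at most, without KO library 4) lost their call. Each lost it in 3 of the 8 such fits. In the other settings the oxidant enzymes lost it in 7 and the immediate early genes in 3, the estimated correlation included. As many as 16 lists were also reached by other splits of the 8 libraries, 8 of 35 splits with the real one included, so chance was not excluded for the number of neutrophil lists. When the linear values were rescaled to a common sum per library, the median log2 fold change of all genes moved from 0.06 to -0.69, and 367 genes were higher and 6442 lower.

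**Figure D2:**
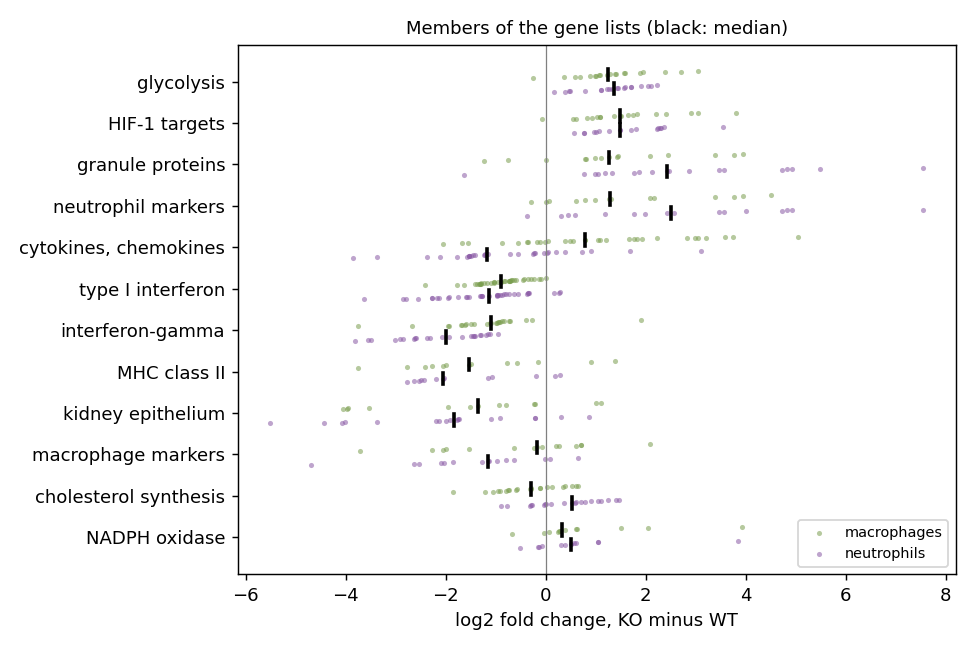
Log2 fold change (KO minus WT) of each tested member of 12 gene lists in macrophages and neutrophils, with 1 point per gene and a black line at the median. Medians lay on the same side of 0 in both cell types for all lists shown except cytokines and chemokines (0.79 in macrophages, -1.18 in neutrophils) and cholesterol synthesis (-0.30, 0.53). With values rescaled to a common sum the neutrophil medians of cholesterol synthesis and NADPH oxidase were -0.32 and -0.44.

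The third comparison tested whether the genotype effect differed between the cell types, as the macrophage effect minus the neutrophil effect. The cytokine gene Il1a and the chemokine gene Cxcl1 rose in KO macrophages and fell in KO neutrophils, and Cxcl3 rose in macrophages and did not pass in neutrophils. Among 9123 genes tested in both cell types, 773 passed limma at an adjusted p below 0.05, with 409 positive and 364 negative differences. The genes named next have a mean over the 16 libraries at or above the median of tested genes, a limit that leaves out some large differences such as those of Stfa3 (-4.49) and Htra4 (4.10). Within it Il1a, an alarm cytokine, had the largest difference (5.02 ± 0.71 (SE), adjusted p = 6.51e-04), with log2 fold changes of 3.57 in macrophages (adjusted p = 0.012) and -1.45 in neutrophils (adjusted p = 0.00167). Cxcl1 behaved alike (4.29 ± 0.34 (SE), adjusted p = 5.79e-06), at 3.05 in macrophages and -1.24 in neutrophils (adjusted p = 2.76e-04). For Cxcl3 (4.67 ± 0.57 (SE), adjusted p = 2.41e-04), the cyclooxygenase Ptgs2 (3.85 ± 0.66 (SE), adjusted p = 0.00246) and the cystine transporter Slc7a11 (3.50 ± 0.34 (SE), adjusted p = 4.24e-05) the macrophage effect was the more positive as well. Cxcl10 (3.50 ± 0.71 (SE), adjusted p = 0.00682) fell in neutrophils and did not pass in macrophages (-0.36, adjusted p = 0.713). In the other direction, Cd177 (-4.83 ± 0.49 (SE), adjusted p = 7.32e-05), Ngp (-4.16 ± 0.65 (SE), adjusted p = 0.00141) and Ifitm6 (-3.95 ± 0.55 (SE), adjusted p = 5.52e-04) rose in neutrophils with a larger effect than in macrophages, where only Ngp passed. Ly6c2 fell in macrophages alone (-3.66 ± 0.46 (SE), adjusted p = 2.59e-04), with -0.06 in neutrophils (adjusted p = 0.899). As a list, cytokines and chemokines differed most between cell types (adjusted p = 1.46e-13, and 0.067 with an estimated correlation, camera). Cholesterol synthesis (adjusted p = 4.18e-04, and 0.195 with an estimated correlation), granule proteins (adjusted p = 1.42e-04, and 0.303 with an estimated correlation), interferon-gamma genes (adjusted p = 9.78e-04, and 0.303 with an estimated correlation) and kidney epithelial markers (adjusted p = 0.00152, and 0.323 with an estimated correlation) differed with the preset correlation. In the same way NF-kB responses (adjusted p = 2.19e-05, and 0.373 with an estimated correlation), C-type lectin and Toll-like receptor sensing (adjusted p = 6.47e-04, and 0.303 with an estimated correlation), macrophage markers (adjusted p = 0.00667, and 0.303 with an estimated correlation), resident macrophages (adjusted p = 0.00994, and 0.303 with an estimated correlation), neutrophil markers (adjusted p = 0.0123, and 0.567 with an estimated correlation) and complement (adjusted p = 0.0219, and 0.286 with an estimated correlation) differed. On simulated data 9.95% of the calls of this test were unchanged genes, above the nominal level. The count was 1587 without WT macrophage library 1, 460 without KO macrophage library 1, 509 without WT neutrophil library 1, 501 without KO neutrophil library 1 and 479 without KO neutrophil library 2.

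Effects in the 2 cell types were also compared gene by gene. The genes that rose in both included Ngp, Mmp8, Hilpda, Nos2 and Il10, and those that fell in both included Miox, Apoe, Kap, Stat1 and H2-DMb1. Ngp and Mmp8 are genes of neutrophil granules, and Miox and Kap are genes of kidney tubules. Whether RNA of those cells in the sorts gave these changes was not tested, so they need not be changes in both cell types. Of the genes tested in both cell types, 373 passed in both. Of them, 204 were higher in KO in both, where independent lists would share 80.9, 143 were lower in both, where 38.0 would be shared, and 26 went opposite ways. Relabelled genotypes alone gave Pearson r of -0.447 to 0.540 between the cell types. Genes thus move together, and the expected numbers are no test of a shared response. Across 9123 genes, which are not independent replicates, the effects had Pearson r = 0.423 (p = 0.0792) and Spearman rho = 0.308 (p = 0.208) in a permutation test with 100 drawn relabellings of genotype within each table, two-sided. The correlation therefore did not pass the threshold. It passed without WT macrophage library 1 (r = 0.525, permutation p = 0.0099), without KO macrophage library 3 (r = 0.440, permutation p = 0.0495) and without WT neutrophil library 4 (r = 0.443, permutation p = 0.0396).

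**Figure D3:**
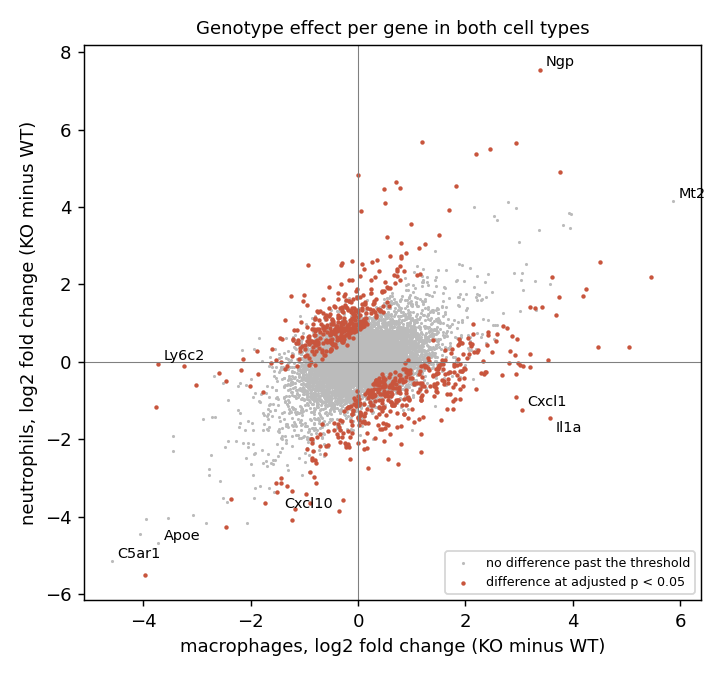
Log2 fold change (KO minus WT) of each gene in macrophages (horizontal axis) and neutrophils (vertical axis), with 1 point per gene for 9123 genes. The 773 genes with a difference at an adjusted p below 0.05 are red, and Ngp, Mt2, Cxcl1, Il1a, Cxcl10, Ly6c2, Apoe and C5ar1 are named.

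Genes near C5ar1 on chromosome 7 were listed because alleles linked to a targeted locus can be carried along with it. The labels give no strain background. Apoe, among the largest falls in both cell types, lies within 5 Mb, at 19696109 to 19699188 (GRCm38). In macrophages 8 of 66 tested genes within 5 Mb passed, 1 higher and 7 lower. Pvr rose (2.32 ± 0.22 (SE), adjusted p = 0.00128), and the lower genes were Apoc2 (-2.77), Apoe (-3.72), Ccdc61 (-1.51), Irf2bp1 (-1.07), Ppm1n (-1.38), Slc1a5 (-0.93) and Sympk (-1.14). Calls were lost without a single library for Apoc2 (adjusted p = 0.051 without KO library 2), Ccdc61 (adjusted p = 0.102 without KO library 1), Irf2bp1 (adjusted p = 0.144 without KO library 1), Ppm1n (adjusted p = 0.138 without KO library 2), Slc1a5 (adjusted p = 0.119 without KO library 1) and Sympk (adjusted p = 0.106 without KO library 1). Of the 8 such fits, the call was lost in 7 for Irf2bp1 and Slc1a5, 6 for Sympk, 5 for Ccdc61 and Ppm1n, and 2 for Apoc2. In neutrophils 26 of 58 passed, 16 higher and 10 lower. The lower genes were Apoc1 (-1.76), Apoc2 (-2.92), Apoe (-4.69), Ccdc61 (-0.92), Irf2bp1 (-0.56), Ppm1n (-1.30), Slc1a5 (-0.58), Tomm40 (-0.46), Trim28 (-0.98) and Zbtb45 (-0.59). The higher genes were Ap2s1 (0.84), Calm3 (0.76), Chmp2a (1.04), Dhx34 (0.48), Eml2 (1.36), Ercc1 (2.02), Gemin7 (0.51), Inafm1 (0.49), Lig1 (0.51), Napa (0.98), Opa3 (0.72), Pglyrp1 (2.47), Ppp1r13l (1.21), Pvr (1.10), Sae1 (0.63) and Ube2m (0.96). Here the calls lost were those of Dhx34 (adjusted p = 0.0636 without WT library 2), Gemin7 (adjusted p = 0.0962 without WT library 1), Inafm1 (adjusted p = 0.058 without KO library 1), Lig1 (adjusted p = 0.0711 without KO library 1), Opa3 (adjusted p = 0.0555 without WT library 1), Slc1a5 (adjusted p = 0.0786 without WT library 1) and Tomm40 (adjusted p = 0.13 without WT library 1). Lig1, Slc1a5 and Tomm40 lost it in 5 of the 8 fits, Gemin7 in 4, Dhx34 and Opa3 in 3, and Inafm1 in 1. Of the higher ones Ap2s1, Calm3, Dhx34, Gemin7, Inafm1, Lig1, Opa3 and Sae1 had a negative value when the values were rescaled to a common sum.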

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

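The test of scaling by S100a8 and S100a9, the share read from the C1q genes, and the reading of the medians without WT macrophage library 1 against 0.5 alone were chosen after the results had been seen, and the other tests in this part were set beforehand.

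The fall of interferon-gamma and MHC class II genes in KO neutrophils came with a fall of macrophage markers, so RNA of macrophages in the WT neutrophil sort is a technical explanation, although the Ly6G+ CD11b+ gate, with a purity above 90% per the labels, should remove Ly6G-negative macrophages. It was tested with the median ratio of WT neutrophil to WT macrophage level over macrophage markers (13.3%) as the share, which is more than that purity leaves if all cells carry equal RNA. For the interferon-gamma genes that share covered a median of 0.194 of the fall, too little to account for it (95% bootstrap interval over markers and genes 0.0332 to 0.333). The median effect over all tested genes was 0.0578. It cannot decide on a general shift of scale by S100a8 and S100a9, because the deposited neutrophil libraries all had medians of 2.75 to 2.81. Markers of kidney epithelium, dendritic cells and natural killer cells fell too, and RNA of those cells was not tested. An effect of the genotype is therefore 1 hypothesis among others, found and tested on the same data. For the MHC class II list the 13.3% share covered 2.70 of the fall (0.424 to 3.69). At a median log2 fold change of -2.06 that is more than the whole WT neutrophil level, so this share is too high for these genes. RNA carried over from macrophages remains a candidate explanation of that part only at a smaller share. Against it, Cd81 (0.09, adjusted p = 0.681), whose ratio sets the share, Mafb (-0.02, adjusted p = 0.949) and Mertk (0.65, adjusted p = 0.179) did not fall past the threshold while the other 8 of these 11 markers did, and at the 2.29% given by C1qc, the highest of the C1q genes, it covered 0.462. 

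The glycolysis and HIF-1 target lists were shifted higher in KO macrophages with the preset correlation (adjusted p = 0.159 for both with an estimated correlation), and WT library 1 lay low for Slc2a1, Ldha and the HIF-1 targets. RNA of neutrophils in the KO sort, with a share of 0.618% from S100a8 and S100a9, covered a median of 0.0156 of the rise (0.00961 to 0.0210), too little to account for it. Without WT library 1 the list medians were 1.11 (0.880 to 1.37) and 1.24 (0.943 to 1.71), and 17 of 20 glycolysis and 15 of 19 HIF-1 members rose, against 10 and 11 with it. The intervals resample the genes of each list, which move together, and do not measure the spread between mice. Both medians lie above the 0.5 below which they had to drop if that library were the cause. That library was therefore not the whole cause of the shift among these libraries. The intervals reach below the bound of 1 also set beforehand, so a smaller part from it stays open. An effect of the genotype is a hypothesis found and tested on the same data.

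Apoe, which fell in both cell types, lies within 5 Mb of C5ar1, so passenger alleles linked to the deletion are a candidate explanation. Genes within 5 Mb passed the threshold 2.10 times as often as other genes in macrophages (12.1% against 5.77%, Fisher's exact p = 0.0556) and 1.02 times as often in neutrophils (44.8% against 43.9%, Fisher's exact p = 0.895). Linked alleles and an effect of the receptor on these genes cannot be told apart, because the cell types gave different ratios and no label or value shows whether the KO mice carry linked alleles. Neighbouring genes are not independent, so these p values describe the region only.

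Chance was weighed by other splits of the libraries. For macrophages 1 of 35 splits, the real one, gave as many as 630 genes, the highest other count being 1, and for neutrophils 1 of 35 gave as many as 4246, the highest other being 6. For the difference between cell types 1 of 100 relabellings, the real one, gave as many as 773 genes, the highest other being 67. Each relabelling also breaks up the genotype effect within each cell type, so it cannot decide on chance for the difference alone. Chance is excluded at 0.05 for the counts of 630 macrophage and 4246 neutrophil genes. The same holds for the number of macrophage lists that passed with the preset correlation, 22, which 1 of 35 splits reached. The other splits still passed 2 to 17 lists, so the count decides nothing about any single list. Adjusted p values with the preset correlation are thus too small to be read alone. With an estimated correlation 0 passed (lowest adjusted p 0.159). Chance was not excluded for the number of neutrophil lists, where 8 of 35 splits gave 16 or more and the highest other was 21.

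A single library lay far from the other 3 of its group in 20 of 310 groups tested by Dixon's criterion (6.45%), and chance alone marks about 1 group in 20. WT macrophage library 1 accounted for 11 of them. Its values were Mt2 6.32 (others 3.12 to 3.62), Saa3 11.47 (others 7.62 to 8.19), Apoe 13.85 (others 11.10 to 11.34), Apoc2 4.77 (others 2.47 to 2.86) and Lars2 14.28 (others 6.56 to 7.72), all above the rest. Below the rest were Slc2a1 4.44 (others 5.99 to 6.27), Ldha 8.55 (others 9.16 to 9.25), Sod2 5.12 (others 6.19 to 6.40), Gbp8 2.53 (others 3.74 to 3.99) and the mean of the HIF-1 targets, 2.92 (others 3.49 to 3.52). It also held 142 (others 10 to 31) tested genes at 0. The MHC class II mean of WT macrophage library 4 was 7.33 (others 7.80 to 7.83), and Il10 in KO macrophage library 2 was 5.37 (others 4.15 to 4.31). In neutrophils C5ar1 of WT library 4 was 9.81 (others at most 9.11). KO library 3 had Cd74 7.11 (others 6.57 to 6.63) and Irf2bp1 2.00 (others 1.55 to 1.62). KO library 2 had Gemin7 6.42 (others 6.02 to 6.05), Lig1 1.82 (others 1.98 to 2.01) and Opa3 4.67 (others 4.06 to 4.15). The epithelial marker mean of KO library 4 was 1.15 (others 1.73 to 1.83).

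The KO effect differed between cell types for 773 genes in the limma test of the difference. Among the named genes it was more positive in macrophages, by the log2 difference given, for Il1a (5.02), Cxcl3 (4.67), Cxcl1 (4.29), Ptgs2 (3.85), Slc7a11 (3.50), Cxcl10 (3.50), Il1r2 (1.93), Htra4 (4.10), Cxcl13 (2.37), Slc16a3 (1.46), Sod2 (1.43), Hvcn1 (1.64), Miox (1.54), Pck1 (1.81), Cxcl11 (2.87), Gbp5 (2.64), Ifi47 (2.73), Gbp3 (3.29) and Cd40 (2.34). It was more negative in macrophages for Cd177 (-4.83), Ngp (-4.16), Ifitm6 (-3.95), Ly6c2 (-3.66), Mmp8 (-1.16), Ltb (-2.41), Clec12a (-2.31), Ciita (-2.60), Stard4 (-2.09), Srebf2 (-2.42), Dhcr24 (-1.54), Sympk (-1.04), Stfa3 (-4.49), Bcl2l15 (-2.72), Chil3 (-3.04), Orm1 (-3.18), Stfa2 (-2.72), Gpi1 (-1.56), Higd1a (-1.16), Rac2 (-0.98), Dhx34 (-1.13), Ercc1 (-1.34), Gemin7 (-1.42) and Opa3 (-1.23). For lists the adjusted p of this difference by camera with the preset correlation was below 0.05: granule proteins (1.42e-04), C-type lectin and Toll-like receptor sensing (6.47e-04), complement (0.0219), cytokines and chemokines (1.46e-13), NF-kB responses (2.19e-05), interferon-gamma genes (9.78e-04), cholesterol synthesis (4.18e-04), resident macrophages (0.00994), neutrophil markers (0.0123), macrophage markers (0.00667) and kidney epithelial markers (0.00152), and 0 of these lists passed with an estimated correlation.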

How the results depend on the processing

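The Y-linked settings, the gene by gene weights, the rescaling to a common sum and the fit without WT library 1 with the Y-linked covariate were chosen after seeing the data, and the other alternatives were planned.

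The fall of C5ar1 kept its direction and its side of the threshold under every alternative run, at -4.97 to -3.55 in macrophages and -6.06 to -4.59 in neutrophils. The macrophage count of 630 genes was the least stable. It was 5596 with sample weights, whose estimate did not converge, and 4042 with weights gene by gene. It was 1119 at an adjusted p below 0.10, 326 with the stricter filter, which tests fewer genes, 1543 in 1 fit of all 16 libraries and 46 with a minimum fold change. Leaving out 1 library gave 166 (without KO library 1) to 1882 (without WT library 1). Libraries lacking Y-linked transcripts, with 1 WT library whose spread was assumed like that of the KO libraries, gave 7048 genes and 11 lists. The neutrophil count of 4246 was 2231 with the stricter filter, 2122 in 1 fit of all 16 libraries, 287 with a minimum fold change, 1256 in libraries with Y-linked transcripts alone and 3368 to 4449 when 1 library was left out. Rescaling to a common sum gave 6809 genes (367 higher, 6442 lower), because KO libraries have the larger sums and the median of all genes moved to -0.69. Under it Ap2s1 (-0.0911), Calm3 (-0.15), Dhx34 (-0.17), Gemin7 (-0.41), Inafm1 (-0.00515), Lig1 (-0.13), Opa3 (-0.15) and Sae1 (-0.23) reversed, and 55 of the other neutrophil named genes kept their call while 7 lost it. The difference between cell types (773) gave 353 genes with the stricter filter and 460 to 1587 when 1 library was left out. With an estimated correlation 0 lists passed in macrophages and 0 in neutrophils. The following counts of lost calls in macrophages include that setting and leave aside the fits without 1 library. The granule protein, neutrophil marker, cholesterol synthesis and both interferon lists each lost their call in 2 settings. Oxidant enzymes lost it in 4 and macrophage markers in 6. Leaving out 1 library gave 19 to 23 macrophage lists and 14 to 18 neutrophil lists. The ribosomal protein list reversed to a median of 0.0243 in macrophage libraries with Y-linked transcripts and equally without WT library 1 with the Y-linked covariate. The correlation of effects (0.423) ranged from 0.371 to 0.525, the highest without WT macrophage library 1. For results whose change has no reason given here, the cause was not tested.

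The mouse numbers were not taken as a pairing, because not every same-numbered pair of libraries deviated together (correlation above 0.1). The deviations of same-numbered WT and KO macrophage libraries correlated at 0.04, 0.14, 0.05 and 0.08, and each WT library correlated best with its own number, a hint from the data and not from the design. In neutrophils the values were 0.00255, 0.13, 0.19 and 0.06. Between macrophages and neutrophils of the same number they were -0.27, -0.07, -0.36 and 0.35 in WT, where only number 4 correlated best with its own number, and 0.14, 0.41, 0.21 and 0.08 in KO, where numbers 1, 2 and 3 did. With the replicate block 244 macrophage genes, 4220 neutrophil genes and 466 differences passed. Depth limits low genes most in WT macrophage library 1, but it is unknown, so no limit in reads is given. The stricter filter gave no value for 15 of 51 macrophage and 16 of 70 neutrophil named genes, which it removed.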

Other observations

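The test of dividing precursors and that of macrophage RNA in the cell cycle list were chosen after the result had been seen, and that of less aged neutrophils was set beforehand.

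Mt1, a metallothionein gene chosen after its values were seen, rose by 3.37 in macrophages (adjusted p = 0.0207, limma) and by 3.40 in neutrophils (adjusted p = 3.57e-05, limma). Mt2, named for macrophages, also rose in neutrophils, by 4.14 (adjusted p = 4.48e-06, limma), a value chosen in the same way. In neutrophils Retnlg, a marker of mature neutrophils, rose by 4.01 (adjusted p = 2.83e-06) and the chemokine receptor Ccr2 fell by 3.21 (adjusted p = 1.20e-04), both chosen in the same way. Of the 26 genes that passed in both cell types in opposite directions, 19 were higher in macrophages and lower in neutrophils and 7 were the reverse.

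The rise of granule genes in KO neutrophils led to 2 hypotheses. If the KO neutrophils were less aged, Sell and Cxcr2 would be higher and Cxcr4 and Icam1 lower. Only 1 of these 4 genes passed in the predicted direction, Cxcr4 (-1.37 ± 0.21 (SE), adjusted p = 3.09e-04), while Sell (0.08, adjusted p = 0.759), Cxcr2 (0.45, adjusted p = 0.0892) and Icam1 (-0.68, adjusted p = 0.0676) did not pass, so less aged neutrophils remain possible and are not shown. If immature dividing precursors were the source, cell cycle genes would be higher, but their median effect was -0.57 (95% bootstrap interval over genes -0.74 to -0.42). That does not exclude such precursors, because loss of macrophage RNA could hide a rise of these genes. The macrophage share of 13.3% covered 5.52 of the fall of 12 cell cycle members (0.946 to 7.25), more than their whole WT level, so it is too high for them. The 2.29% given by C1qc covered 0.946.

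Y-linked transcripts were present in some libraries of every group, and the labels give no sex. In macrophages Ddx3y lay at 0.44 in WT library 1, 3.76, 4.27 and 4.44 in WT libraries 2, 3 and 4, 0.10 in KO libraries 1 and 2, and 4.29 and 4.56 in KO libraries 3 and 4. In neutrophils it lay at 0.05 and 0.08 in WT libraries 1 and 2, 4.54 and 5.02 in WT libraries 3 and 4, 0.05 and 0.03 in KO libraries 1 and 2, and 4.71 and 4.80 in KO libraries 3 and 4. The WT libraries numbered 2 thus differed between the cell types.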
